A study of Rattus norvegicus with 9 samples.

How the data were processed

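Total RNA of cultured rat aortic vascular smooth muscle cells was isolated with a miRNeasy kit, and small RNA libraries were made with the QIAseq small RNA kit and sequenced on a NextSeq as single reads of 75 nt, per the labels' protocols. The protocol text, the same for each sample, describes 24 h of serum starvation before treatment, PDGF-BB at 30 ng/ml for 24 h, and a planned depth of 30 M reads per sample. The genome build was Rnor_6.0, per the submitters' processing notes. The aligner, the counting tool, the miRBase release and whether reads were collapsed by molecular identifier are not given in the sources used here. The values are raw counts per mature rat miRNA, as deposited by the authors. They are whole numbers with totals that differ between samples, and nothing in the table was normalized.

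Samples were grouped by their titles into differentiated, PDGF-BB and H3K4me2-edited cells, with replicates 1 to 3 in each. The titles' sample names matched the columns of the table, and 0 columns belonged to other samples. Names are printed without the rat prefix. A count in this kit can be a read or a molecule, so counting intervals and floors cover counting error only. The count totals, from 1783409 to 11392178, are well under the planned reads. They hold only counts assigned to mature miRNAs, and why they are lower is not given in the sources used here. A floor of 3 counts, the upper limit that a count of 0 allows, corresponds to 1.99 CPM in differentiated replicate 1 and 0.205 CPM in edited replicate 2. Between 381 and 437 miRNAs had a count in a library. Members of a family with near-identical sequences, such as let-7 or the 5p arms of miR-146a and miR-146b, may share reads, and how the authors' counting split them is not given in the sources used here.

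Replicates of one group differed by more than sampling noise, with chi-square values per degree of freedom from 16.0 to 680 and correlations of log2 CPM across miRNAs from 0.984 to 0.996, so none was counted as a repeat of another. The labels do not say that equal replicate numbers share anything, so the model has no term for the number and a fit with one is an alternative. Samples with equal numbers deviated together in 4 of 9 pairs, although the highest correlation lay between unlike numbers, so a shared source is neither shown nor excluded.

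All 9 libraries entered one edgeR 4.0.16 quasi-likelihood model in R 4.3.3 with a mean per group, TMM factors, and the edgeR filter for low counts with its minimum of 10 counts. The filter kept 304 miRNAs and left out 198 that had a count and 260 that had none. TMM factors were from 0.847 to 0.913 in differentiated, 0.912 to 1.03 in PDGF-BB and 1.15 to 1.29 in edited libraries, and the common biological coefficient of variation was 0.179. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05 and no minimum fold. SE is the absolute log2 fold change divided by the square root of the F statistic. The 3 comparisons were PDGF-BB against differentiated, edited against differentiated and edited against PDGF-BB. Principal components were computed on log2 CPM with a prior count of 2.

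Lists of miRNAs were fixed before the data were examined, as were the groups, the tests, the rule for named miRNAs and the alternatives, except thinning. The 18 lists are muscle miRNAs under serum response factor and myocardin (called the muscle list), miRNAs linked to smooth muscle proliferation, injury or de-differentiation, the miR-15/16, let-7, miR-29, miR-30 and miR-34 families, the X-linked cluster of miR-322 and miR-503, the miR-17/92, miR-23/27/24 clusters, the miR-199 and miR-214 group, the Dlk1-Dio3 cluster, hypoxia (miR-210), NF-kappaB-linked miRNAs, and endothelial, blood, epithelial and neural markers. Several share members: miR-146a, miR-146b and miR-155 are in the de-differentiation and NF-kappaB lists, miR-24 in the de-differentiation and miR-23/27/24 lists, and miR-322 and miR-503 in the miR-15/16 and X-linked lists. A list holds each arm of its miRNAs. The muscle list also holds miR-206, a skeletal muscle miRNA, so the regulators in its description may not hold for that member. Of 88 arms of the Dlk1-Dio3 cluster 37 had a count and 1 was tested, and the hypoxia and endothelial lists had 1 and 2 tested arms, so these 3 lists have no list test. The other 15 were tested with fry and camera of limma 3.58.1, camera with a preset correlation of 0.01 and with an estimated one, and p-values were adjusted over the lists. The fry p tests whether the arms of a list move one way on balance, and neither it nor its test of change in either direction compares a list with other miRNAs. Camera with an estimated correlation passed 0 lists in each comparison, with 0, 1 and 1 at an unadjusted p under 0.05, while with the preset correlation it passed 2, 1 and 7.

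The miRNAs named per comparison were drawn from the 5 with the largest rise and the 5 with the largest fall among those that passed and whose libraries do not overlap between groups, the 10 most abundant, each tested arm of the muscle and de-differentiation lists, and of each other list up to 2 arms with the smallest adjusted p. miR-7a-5p, miR-181a-1-3p and the miRNAs called in opposite directions were named in addition, as were the epithelial arms that rose and arms set beside a named one, and those under other observations, all chosen after their values were seen.

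The edgeR step was tested on simulated data with 200 changed miRNAs, drawn from the means and totals of these libraries. Percentages are of the changed miRNAs that the filter kept, which were fewer than the simulated ones. It recovered 88.9% (40 of 45) of log2 changes of 1 and 97.7% (43 of 44) of changes of 2 for PDGF-BB against differentiated, 71.4% (25 of 35) and 97.8% (44 of 45) for edited against differentiated, and 80.4% (37 of 46) and 100.0% (40 of 40) for edited against PDGF-BB. Of the unchanged miRNAs it called 2 of 215, 0 of 228 and 3 of 216. The simulated rises and falls were equal in number and placed on random miRNAs. They do not test the scaling of libraries whose composition differs, as in the edited comparisons.

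Alternatives were median-ratio factors, library totals alone, scaling without the 5 most abundant miRNAs, no filter, at least 10 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the 6 compared libraries only, a block for the replicate number, an adjusted p of 0.01, a fold of at least 2, each library left out in turn, and counts thinned to the smallest total. Overlap between unchanged groups that share controls was simulated 100 times. Neighbouring hairpins were found from RefSeq names in the rat assembly GRCr8, which is not the build of the counts, so no coordinates are printed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.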

Results

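Small RNA was sequenced from cultured rat aortic vascular smooth muscle cells in 3 states, with 3 libraries each. Differentiated cells received no treatment. PDGF-BB cells received platelet-derived growth factor BB, a mitogen of smooth muscle, at 30 ng/ml for 24 h. H3K4me2-edited cells were transduced with a lentivirus carrying a sequence that the labels call Myocardin-F-LSD1. Myocardin is a co-activator of contractile genes in smooth muscle, and LSD1 is a demethylase of lysine 4 of histone H3. The protocol also gives 24 h of serum starvation before treatment, and whether that applies to differentiated and edited cells is not stated, so starvation may be part of the PDGF-BB comparisons. The titles call both the PDGF-BB and the edited cells de-differentiated. Libraries from cells with an empty lentivirus were not analysed here, so the edited cells differ from the others by the transduction as well as by the construct.

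The table holds counts for 762 mature rat miRNAs, of which 502 had a count in some library and 304 were abundant enough to test. Library totals were 1783409, 3850232 and 2138720 counts in differentiated cells, 1982051, 2646089 and 3568888 in PDGF-BB cells, and 3149262, 11392178 and 7359735 in edited cells. Levels are given below as CPM scaled by TMM factors, as mean ± SD over n = 3 libraries. Changes are log2 fold changes ± SE from the edgeR quasi-likelihood test. The labels do not say that the replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical.

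miR-143-3p, a smooth muscle miRNA, was the most abundant miRNA over the 9 libraries together. It was the most abundant within each differentiated library and PDGF-BB replicates 1 and 2, while miR-125b-5p led in PDGF-BB replicate 3 and edited replicate 3 and miR-21-5p in edited replicates 1 and 2. miR-143-3p took 18.3% to 20.4% of the counts in differentiated libraries, 12.9% to 15.1% in PDGF-BB libraries and 3.93% to 6.79% in edited libraries. The 5 miRNAs most abundant over the 9 libraries held 53.2% to 55.8%, 49.4% to 52.0% and 34.2% to 43.9% of counts in the same order of groups. The first principal component of log2 CPM carried 72.8% of the variance and separated the edited libraries, at 7.95, 15.95 and 16.49, from the differentiated libraries, at −8.73, −6.37 and −7.74. PDGF-BB libraries lay at −6.79, −6.27 and −4.49. Edited replicate 1 lay nearer the other groups than edited replicates 2 and 3.

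Marker miRNAs of other cell types were counted in each group. miR-126a arms, markers of endothelium, summed to 1998 ± 208 CPM in differentiated, 1855 ± 56.2 in PDGF-BB and 3070.0 ± 241 in edited cells. Neural marker miRNAs, led by miR-9a, summed to 61.2 ± 2.32, 56.8 ± 3.46 and 185 ± 8.90 CPM. Blood cell markers summed to 58.8 ± 13.0, 57.3 ± 8.28 and 89.5 ± 11.3 CPM, and epithelial markers to 479.9 ± 37.1, 465 ± 36.4 and 344 ± 40.7 CPM.

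The first comparison asks which miRNAs differ after PDGF-BB. Among abundant miRNAs, the rises included those of miR-7a-5p, from 1208 ± 77.7 to 2703 ± 137.2 CPM, miR-29b-3p, from 3607 ± 448 to 8096 ± 1201, and miR-146b-5p, from 1955 ± 601 to 5037 ± 659.8. miR-221-3p, which is linked to smooth muscle proliferation, rose from 5207 ± 1247 to 10493 ± 975 CPM, a log2 fold change of 1.01 ± 0.16. miR-145-3p fell from 1073 ± 75.1 to 652 ± 82.0 CPM, and miR-145-5p from 10853 ± 361 to 7068 ± 1059. miR-143-3p, at 149015 ± 20633 CPM against 220263 ± 17804, did not pass, with a log2 fold change of −0.56 ± 0.18 and an edgeR adjusted p of 0.0928. It passed with the DESeq2 test, with the 6 compared libraries alone and without the filter for low counts.

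Among the 31 miRNAs that passed, the largest log2 rises were those of miR-3558-5p (2.63 ± 0.47, edgeR adjusted p = 0.00888), miR-222-5p (2.45 ± 0.32, 0.00280), miR-129-5p (2.25 ± 0.43, 0.00986), miR-147 (2.11 ± 0.53, 0.0324) and miR-181b-1-3p (1.57 ± 0.30, 0.00986). miR-3558-5p rests on 44 counts over the 3 PDGF-BB libraries and 6 over the 3 differentiated libraries. The largest log2 falls were those of miR-200a-3p (−1.20 ± 0.30, edgeR adjusted p = 0.0324), miR-145-3p (−0.72 ± 0.12, 0.00888), miR-143-5p (−0.65 ± 0.16, 0.0319), miR-145-5p (−0.62 ± 0.14, 0.0255) and miR-101a-3p (−0.50 ± 0.13, 0.0418). Of the 9 fits that leave out 1 library, the call was kept in 9 for miR-222-5p, 8 for each of miR-3558-5p, miR-129-5p and miR-145-3p, 7 for miR-181b-1-3p, 4 for miR-145-5p and 3 for each of miR-147, miR-200a-3p, miR-143-5p and miR-101a-3p. In each comparison 3 of the 9 fits leave out a library of the group not compared, which enters only through the shared spread, scaling and filter. A call kept in 3 may thus have been lost in each fit without a compared library. With library totals miR-101a-3p (−0.37) did not pass. miR-7a-5p, kept in 9, had the smallest adjusted p of the comparison, with a log2 fold change of 1.16 ± 0.094 and an edgeR adjusted p of 7.7e-05.

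Of the 6 tested arms of the muscle list, 3 fell (miR-143-5p, miR-145-3p and miR-145-5p), and 4 fell when adjusted over the list alone. The list has 14 arms, of which 9 had a count. Most of its tested arms come from the neighbouring hairpins of miR-143 and miR-145, so they are not independent. The correlation that camera estimated within the list was 0.725. With library totals as the scaling in place of TMM, the falls of miR-143-5p (−0.52) and miR-145-5p (−0.49) kept their sign and no longer passed. The other arms, miR-143-3p, miR-1-3p (−0.93 ± 0.50) and miR-206-3p (−0.69 ± 0.98), did not pass. Of 25 tested arms linked to smooth muscle injury or de-differentiation, 7 rose and 1 fell, the same counts as when adjusted over the list alone. The 7 were miR-221-3p, miR-222-3p (0.99 ± 0.20), miR-222-5p, miR-146b-5p (1.37 ± 0.28), miR-146b-3p (1.51 ± 0.31), miR-181b-1-3p and miR-181b-5p (0.61 ± 0.11). The 1 that fell was miR-26a-5p (−0.44 ± 0.11), which with library totals did not pass (−0.30). The calls were kept in 8 of the 9 fits without 1 library for miR-221-3p (lost without differentiated replicate 3), 5 for miR-222-3p, 6 for each miR-146b arm, 8 for miR-181b-5p and 3 for miR-26a-5p. miR-146a-5p (−0.021 ± 0.46) and miR-21-5p (−0.22 ± 0.15), both abundant, did not pass.

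In the miR-29 family, which targets collagen and elastin transcripts, 3 of 6 arms rose, among them miR-29b-3p (1.17 ± 0.20) and miR-29a-3p (0.50 ± 0.12). Among 6 arms linked to NF-kappaB, 3 rose, which were miR-146b-5p, miR-146b-3p and miR-147. In the miR-23/27/24 clusters 2 of 10 arms rose, miR-23a-5p (1.30 ± 0.34) and miR-27a-5p (0.55 ± 0.15). In the miR-30 family 1 of 11 arms fell, miR-30a-5p (−0.32 ± 0.084, not past with library totals at −0.19), and 2 fell when adjusted over the list alone. Of 8 epithelial marker arms 1 fell, miR-200a-3p, and 3 fell when adjusted over the list alone. Of the 9 fits without 1 library, the calls were kept in 8 for miR-29b-3p, 5 for miR-29a-3p, 3 for miR-30a-5p and 2 for each of miR-23a-5p and miR-27a-5p. No arm passed in the miR-15/16 family (0 of 12), the X-linked cluster of miR-322 and miR-503 (0 of 12), the miR-17/92 clusters (0 of 14, with miR-18a-5p at 0.63 ± 0.19), the let-7 family (0 of 20), the miR-34 family (0 of 6), the miR-199 and miR-214 group (0 of 4), or the blood (0 of 3) and neural (0 of 3) markers. miR-210-3p (−0.28 ± 0.25), induced by hypoxia, the endothelial marker miR-126a-3p (−0.11 ± 0.11) and miR-379-5p (1.27 ± 0.60), the 1 tested arm of the imprinted Dlk1-Dio3 cluster, did not pass. Summed over its arms, most of them under the filter, that cluster lay at 9.74 ± 0.509 CPM in differentiated and 35.4 ± 11.1 in PDGF-BB cells. In edited cells it lay at 8.46 ± 7.33 CPM. These sums were not tested.

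**Figure D1:**
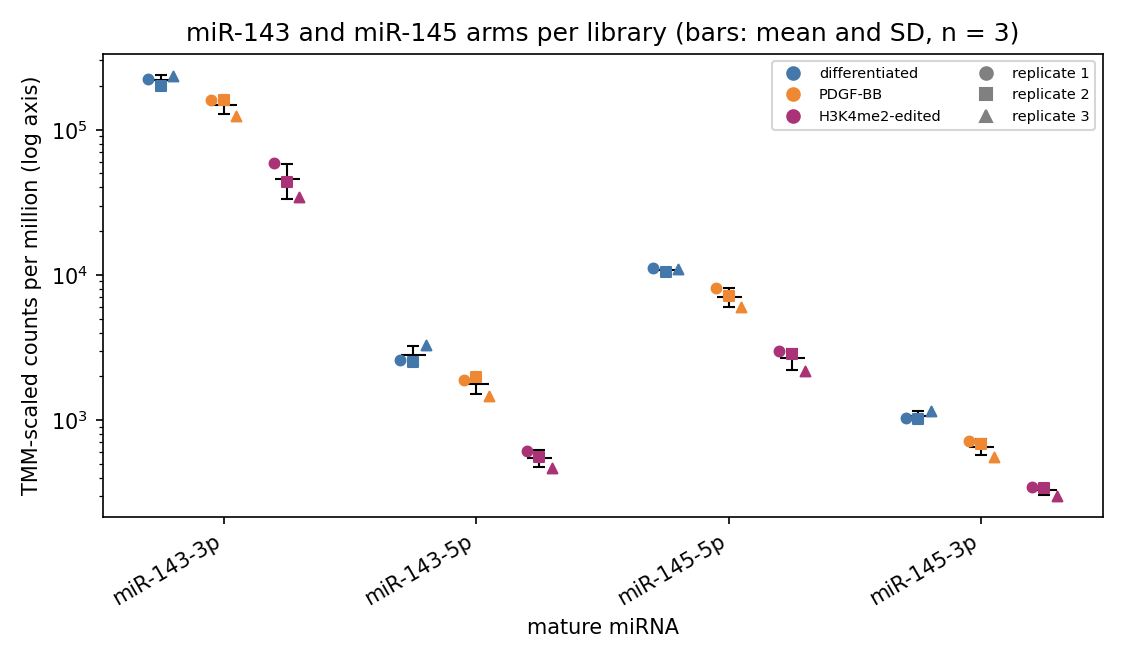
TMM-scaled CPM (log axis) of 4 miR-143 and miR-145 arms in the 9 libraries. Colours mark groups, shapes mark replicates, and bars are mean and SD (n = 3); miR-143-3p lies at 220263 CPM in differentiated, 149015 in PDGF-BB and 45715 in edited cells.

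The edgeR test passed 31 of 304 miRNAs at an adjusted p of 0.05, 22 higher and 9 lower, and 74 at an unadjusted p under 0.05. The 3 values of one group did not overlap the 3 of the other for 107 miRNAs (35.2%, where chance gives 10%). With library totals as the scaling the median of all miRNAs shifted by 0.13 and the split was 24 higher and 2 lower, and with DESeq2 it was 24 and 24 of 48. Without a library the count was 16, 12 and 3 for differentiated replicates 1, 2 and 3 and 12, 12 and 18 for PDGF-BB replicates 1, 2 and 3. For edited replicates 1, 2 and 3, which are not compared here, it was 53, 24 and 32. In each of the 9 fits that leave out 1 library 3 calls were kept (miR-7a-5p, miR-222-5p and miR-181a-1-3p). The fry test on the 15 lists with at least 3 tested arms passed 0, with 6 at an unadjusted p under 0.05 and 7 in its test of change in either direction. Its adjusted p was 0.0806 for the NF-kappaB list, 0.0832 for both the muscle and the de-differentiation list, 0.0865 for each of the miR-29, miR-30 and neural marker lists, and up to 0.958 for the others. With library totals the de-differentiation, NF-kappaB and miR-29 lists passed, and without edited replicate 1 4 lists passed. With a preset correlation camera passed the muscle list (adjusted p = 0.00190) and the de-differentiation list (adjusted p = 0.00520), and both had an adjusted p of 0.564 with an estimated correlation, where camera passed 0 lists, with 0 at an unadjusted p under 0.05.

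The second comparison sets H3K4me2-edited cells against differentiated cells. The smooth muscle miRNAs fell, miR-143-3p from 220263 ± 17804 to 45715 ± 12613 CPM and miR-145-5p from 10853 ± 361 to 2664 ± 438. miR-146a-5p fell from 14605 ± 772 to 1044 ± 765 CPM, while miR-146b-5p rose from 1955 ± 601 to 13581 ± 5321; both are induced by NF-kappaB. The clustered miRNAs miR-182, miR-96-5p and miR-183-5p rose from 58.7 ± 14.7, 25.3 ± 4.52 and 59.4 ± 15.9 CPM to 873 ± 170.1, 305 ± 33.7 and 609.7 ± 65.9 CPM. miR-221-3p fell from 5207 ± 1247 to 2575 ± 224 CPM.

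The largest log2 rises were those of miR-182 (3.87 ± 0.30, edgeR adjusted p = 5.5e-06), miR-296-5p (3.78 ± 0.49, 2.0e-04), miR-296-3p (3.69 ± 0.29, 5.5e-06), miR-96-5p (3.57 ± 0.24, 4.6e-06) and miR-183-5p (3.34 ± 0.30, 1.6e-05). The largest log2 falls were those of miR-1-3p (−5.75 ± 0.71, edgeR adjusted p = 1.4e-04), miR-429 (−5.25 ± 0.43, 7.2e-06), miR-200b-3p (−4.79 ± 0.57, 1.1e-04), miR-200a-3p (−4.69 ± 0.36, 5.5e-06) and miR-672-5p (−4.31 ± 0.51, 1.1e-04). miR-1-3p had 5 counts over the 3 edited libraries (4, 1 and 0 in replicates 1, 2 and 3) against 82 over the 3 differentiated libraries. Among the most abundant miRNAs, miR-125b-5p (−0.90 ± 0.13), miR-21-5p (−0.81 ± 0.15) and miR-31a-5p (−0.47 ± 0.082) fell and miR-199a-3p (0.66 ± 0.13) rose. With library totals the fall of miR-31a-5p (−0.022) did not pass.

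Of the 6 muscle arms 5 fell, also when adjusted over the list alone, with log2 fold changes of −2.27 ± 0.19 for miR-143-3p, −2.36 ± 0.17 for miR-143-5p, −2.03 ± 0.15 for miR-145-5p and −1.71 ± 0.12 for miR-145-3p, besides miR-1-3p. The sixth, miR-206-3p (−1.37 ± 0.95), did not pass. Apart from miR-1-3p, the arms that fell come from the neighbouring hairpins of miR-143 and miR-145, so these falls are not independent. The list passed the fry test (adjusted p = 2.6e-04, and adjusted p = 0.535 by camera with an estimated correlation). Of the 25 de-differentiation arms 7 rose and 14 fell, 7 and 15 when adjusted over the list alone. Those that fell included miR-221-3p (−1.02 ± 0.16), miR-221-5p (−1.48 ± 0.24), miR-222-3p (−1.40 ± 0.20), miR-146a-5p (−3.81 ± 0.52), miR-132-3p (−1.56 ± 0.41), miR-212-3p (−1.64 ± 0.39) and miR-155-5p (−0.73 ± 0.12, which with library totals did not pass at −0.28). Those that rose included miR-146b-5p (2.80 ± 0.29), miR-26a-3p (1.27 ± 0.30), miR-181b-1-3p (1.51 ± 0.28) and miR-24-3p (0.38 ± 0.10). miR-222-5p, at −0.26 ± 0.34, did not pass. The list passed the fry test on balance downwards (adjusted p = 0.0437, and adjusted p = 0.714 by camera with an estimated correlation). It passed in 5 of 17 other settings, with fry adjusted p from 0.00636 to 0.342, and with library totals the direction of the test turned upwards without passing (fry adjusted p = 0.227), while the median went from −0.73 to −0.28.

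**Figure D2:**
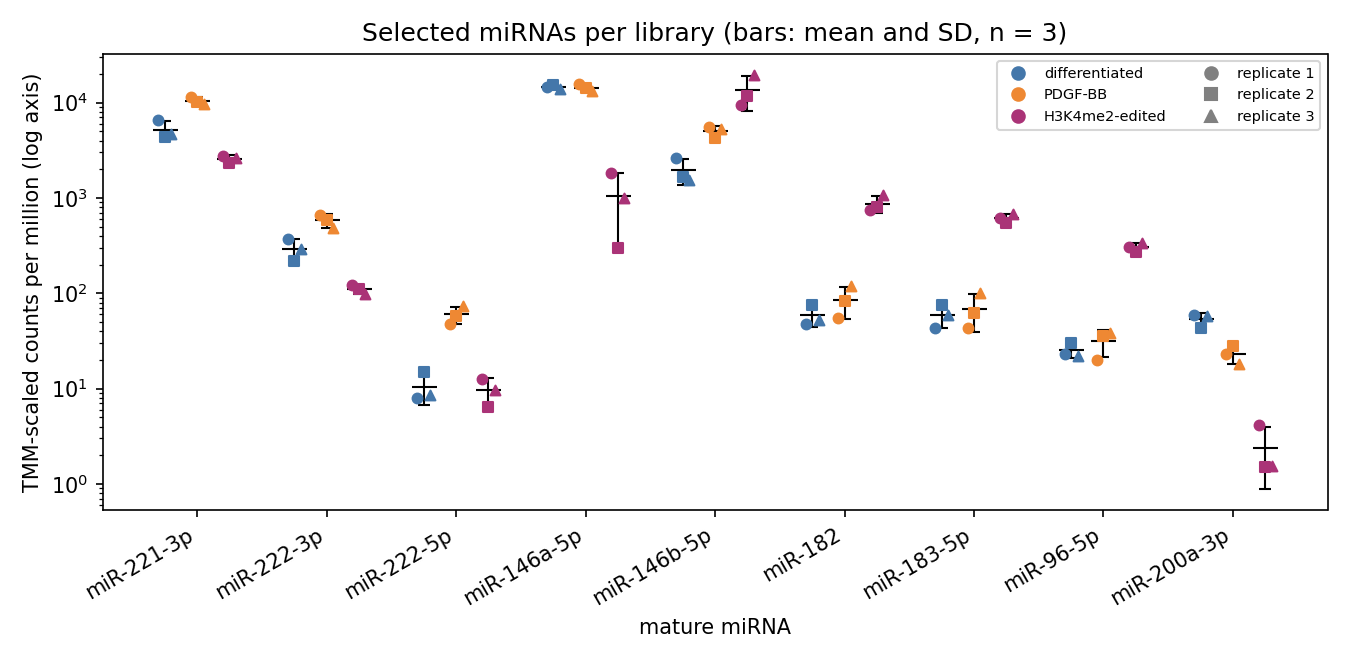
TMM-scaled CPM (log axis) of 9 miRNAs named in the text in the 9 libraries, coloured by group, with replicates as marker shapes and bars as mean and SD (n = 3). miR-221-3p lies at 5207 CPM in differentiated, 10493 in PDGF-BB and 2575 in edited cells, and miR-182 at 58.7, 85.6 and 873.

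Other families rose in edited cells. In the miR-15/16 family, linked to cell-cycle restraint, 8 of 12 arms rose, among them miR-15a-5p (0.73 ± 0.10) and miR-503-5p (1.55 ± 0.38), with a fry adjusted p of 0.00709 and an adjusted p of 0.535 by camera with an estimated correlation. miR-503-5p was at 332 CPM in edited replicate 1, within the 253.5 to 368.8 of differentiated libraries, and at 1214 and 1042 in edited replicates 2 and 3. In the miR-23/27/24 clusters 7 of 10 arms rose, among them miR-27b-3p (1.61 ± 0.19) and miR-23b-3p (1.16 ± 0.14), with a fry adjusted p of 0.00285 and 0.535 with an estimated correlation. The 4 tested arms of miR-199 and miR-214, miRNAs of mesenchymal cells, rose, with miR-199a-5p at 0.76 ± 0.15 and a fry adjusted p of 0.00285, or 0.535 with an estimated correlation. The miR-29 family had 4 of 6 arms higher, 5 when adjusted over the list alone, with miR-29c-3p at 0.96 ± 0.18 and a fry adjusted p of 0.00770, or 0.686 with an estimated correlation. In the miR-30 family 4 of 11 arms rose, with miR-30b-5p at 0.51 ± 0.15 and a fry adjusted p of 0.0482, or 0.792 with an estimated correlation. That list passed in 11 of 17 other settings, with fry adjusted p from 3.0e-04 to 0.128.

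The X-linked cluster of miR-322 and miR-503 had 8 of 12 arms higher, with miR-322-5p at 1.20 ± 0.32, and did not pass the fry test (adjusted p = 0.127, or 0.0330 with library totals). Edited replicate 1 stood apart, with miR-322-5p at 3595 CPM against 10596 and 9633 in edited replicates 2 and 3 and 2917 to 4058 in differentiated libraries, and the list passed when that library was left out. In the miR-17/92 clusters 4 of 14 arms fell, 0 when adjusted over the list alone, among them miR-92a-3p (−0.86 ± 0.24) and miR-17-5p (−0.48 ± 0.16), and with library totals neither fall passed (−0.42 and −0.030) and the median of the list turned from −0.22 to 0.22 (fry adjusted p = 0.277 with TMM scaling and 0.281 with library totals). Their calls were kept in 6 and 4 of the 9 fits without 1 library. Of 20 let-7 arms 1 rose, let-7f-1-3p (0.55 ± 0.21, a call kept in 2 of the 9 fits without 1 library), and 0 when adjusted over the list alone. The let-7 list did not pass (fry adjusted p = 0.356, median −0.092), and with library totals it passed upwards with a median of 0.36 (fry adjusted p = 8.6e-04). The p53-regulated miR-34 family held 3 arms that rose, with miR-34b-3p at 0.90 ± 0.22, and 1 that fell, miR-34a-5p at −0.52 ± 0.12, which with library totals did not pass (−0.060). The miR-34 list did not pass with TMM scaling (fry adjusted p = 0.277), and with library totals it passed upwards with a median of 1.24 (fry adjusted p = 0.00942). Of the 6 arms linked to NF-kappaB 3 rose and 3 fell, with a median of 0.84, a mean of 0.0041 and a fry adjusted p of 0.277. With library totals that list passed upwards with a median of 1.29 (fry adjusted p = 8.2e-04), as it did without differentiated replicate 1, and without edited replicate 2 it passed downwards. miR-210-3p rose from 200.1 ± 44.8 to 453 ± 139 CPM, and miR-379-5p (−1.21 ± 0.68) did not pass.

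Markers of other cell types moved in both directions. The endothelial markers miR-126a-5p (0.70 ± 0.12) and miR-126a-3p (0.60 ± 0.11) rose. miR-9a-5p, a neural marker, rose from 32.4 ± 3.66 to 132.8 ± 2.83 CPM, and the 3 tested neural arms rose together (fry adjusted p = 1.5e-06, and adjusted p = 0.535 by camera with an estimated correlation). Of 8 epithelial arms 4 fell, among them miR-200a-3p, from 53.3 ± 8.46 to 2.40 ± 1.52 CPM, and miR-429. The 3 that rose were miR-141-3p (log2 fold change 1.97 ± 0.44), miR-200c-3p (from 1.39 ± 0.736 to 9.31 ± 4.87 CPM) and miR-203a-3p (1.91 ± 0.62), and the list passed the fry test downwards (adjusted p = 0.00202, or 0.686 with an estimated correlation), also with library totals, where its median turned to 0.11. The call of miR-203a-3p was kept in 6 of the 9 fits without 1 library, and at 2.21 CPM its level in edited replicate 1 was within the differentiated range of 0.854 to 2.71. The blood marker miR-150-5p (1.35 ± 0.28) rose, 1 of 3 tested arms, and that list had a median of −0.52, a mean of 0.070 and a fry adjusted p of 0.905.

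In total 180 of 304 miRNAs passed the edgeR test, 98 higher and 82 lower, and 198 had an unadjusted p under 0.05. The 3 values of one group did not overlap the 3 of the other for 193 miRNAs (63.5%, where chance gives 10%). With library totals the median of all miRNAs shifted by 0.45 and the split was 151 higher and 40 lower. Of the 180 calls 122 (67.8%) were kept in each of the 9 fits without 1 library, and miR-31a-3p (−0.35 ± 0.12), kept in 3 of them, turned to 0.10 with library totals.

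The third comparison sets the edited cells directly against PDGF-BB cells, the other state that the titles call de-differentiated. The arms of miR-221 and miR-222 were lower in edited cells, with miR-221-3p at 2575 ± 224 CPM against 10493 ± 975 and miR-222-3p at 111 ± 11.8 against 580.1 ± 92.7. miR-143-3p was lower as well, at 45715 ± 12613 CPM against 149015 ± 20633. miR-146a-5p was lower at 1044 ± 765 against 14392 ± 1146 CPM and miR-146b-5p higher at 13581 ± 5321 against 5037 ± 659.8. miR-27b-3p was higher at 8495 ± 2192 CPM against 2351 ± 160.3.

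The largest differences upwards were those of miR-296-5p (3.35 ± 0.45, edgeR adjusted p = 2.2e-04), miR-182 (3.33 ± 0.29, 1.8e-05), miR-96-5p (3.26 ± 0.23, 6.5e-06), miR-183-5p (3.12 ± 0.29, 2.7e-05) and miR-296-3p (3.06 ± 0.27, 1.8e-05). The largest downwards were those of miR-1-3p (−4.82 ± 0.76, edgeR adjusted p = 4.5e-04), miR-429 (−4.28 ± 0.45, 3.8e-05), miR-672-5p (−4.21 ± 0.50, 9.9e-05), miR-216a-5p (−4.05 ± 0.84, 0.00191) and miR-146a-3p (−4.04 ± 0.53, 1.9e-04). Over the 3 edited libraries miR-1-3p and miR-216a-5p had 5 counts each, against 49 and 28 over the 3 PDGF-BB libraries. In edited replicates 1, 2 and 3 these were 4, 1 and 0 for miR-1-3p and 3, 2 and 0 for miR-216a-5p.

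Of the 6 muscle arms 5 were lower in edited than in PDGF-BB cells, with miR-143-3p at −1.70 ± 0.19 and miR-145-5p at −1.41 ± 0.14 (fry adjusted p = 0.00112, and adjusted p = 0.469 by camera with an estimated correlation). Most of these arms come from the neighbouring hairpins of miR-143 and miR-145. Of the 25 de-differentiation arms 17 were lower and 5 higher, 18 and 5 when adjusted over the list alone (fry adjusted p = 0.00112, or 0.469 with an estimated correlation). The lower arms included miR-221-3p (−2.03 ± 0.16), miR-222-3p (−2.38 ± 0.20), miR-222-5p (−2.71 ± 0.30), miR-132-3p (−2.22 ± 0.41), miR-212-3p (−2.62 ± 0.36) and miR-21-5p (−0.59 ± 0.15, a call lost without PDGF-BB replicate 1 or 2). miR-181b-5p (−0.29 ± 0.11) passed in the fit of all libraries, in 0 of the 9 fits without 1 library, and turned to 0.030 with library totals. The higher arms included miR-146b-5p (1.43 ± 0.28), miR-26a-5p (0.45 ± 0.11) and miR-24-3p (0.42 ± 0.10).

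Higher families were miR-15/16, with 7 of 12 arms and miR-322-5p at 1.41 ± 0.33 (fry adjusted p = 0.00610, or 0.469 with an estimated correlation), miR-199 with miR-214, 4 of 4 arms and miR-199a-3p at 0.93 ± 0.13 (0.00112, or 0.469), and miR-30, with 6 of 11 arms and miR-30b-5p at 0.63 ± 0.15 (0.00383, or 0.469). The miR-23/27/24 clusters had 5 arms higher and 1 lower of 10, with miR-27b-3p at 1.85 ± 0.19 (fry adjusted p = 0.00677, or 0.633 with an estimated correlation). Neural markers were higher in 3 of 3 arms, with miR-9a-5p at 2.41 ± 0.14 (fry adjusted p = 8.4e-07, or 0.469 with an estimated correlation). Epithelial markers were lower on balance, with 4 arms lower, 2 higher and miR-200a-3p at −3.49 ± 0.36 (fry adjusted p = 0.00913, or 0.710 with an estimated correlation). miR-322-5p at 3595 CPM in edited replicate 1 was close to the 2747 to 3245 of PDGF-BB libraries. In the miR-17/92 clusters 7 of 14 arms were lower, with miR-18a-5p at −1.06 ± 0.18 (fry adjusted p = 0.0463, or 0.710 with an estimated correlation), and that list passed in 2 of 17 other settings, with fry adjusted p from 0.0233 to 0.502. Among NF-kappaB-linked arms 3 were lower and 2 higher (fry adjusted p = 0.0188, or 0.838 with an estimated correlation), and the list passed in 8 of 17 other settings, with fry adjusted p from 0.00400 to 0.182, and with library totals it did not pass and its median turned to 0.017.

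The lists that did not pass the fry test were the X-linked cluster, with 10 of 12 arms higher, 11 when adjusted over the list alone (adjusted p = 0.0656, or 0.0345 with library totals, and past the threshold too with a block for the replicate number or without edited replicate 1), let-7, with 1 arm higher and 1 lower of 20, and 0 when adjusted over the list alone (0.142, although with library totals the list passed upwards with a median of 0.20), miR-29, with 3 higher and 1 lower of 6 (0.217, or 0.0110 with library totals), miR-34, with 2 of 6 lower (0.923, although with library totals neither passed, at −0.084 for miR-34a-5p and −0.43 for miR-34a-3p), and blood, with 1 of 3 higher (0.865, with a median of −0.24 and a mean of 0.16). miR-210-3p (1.45 ± 0.25) and miR-126a-5p (0.81 ± 0.12) were higher and miR-379-5p (−2.48 ± 0.56) was lower in edited cells.

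The edgeR test passed 179 of 304 miRNAs, 85 higher and 94 lower in edited cells, and 190 at an unadjusted p under 0.05. The groups did not overlap for 183 miRNAs (60.2%, where chance gives 10%), and 122 of the calls (68.2%) were kept in each of the 9 fits without 1 library. With library totals the median of all miRNAs shifted by 0.32 and 176 passed, 70.5% of them higher and 52 lower.

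The last question is how far the changes of the PDGF-BB and the edited cells against differentiated cells overlap. Of the 31 miRNAs that passed after PDGF-BB, 15 passed in the same direction in edited cells, among them miR-146b-5p, miR-29b-3p, miR-143-5p and miR-145-5p, and 7 passed in the opposite direction, among them miR-221-3p, miR-222-3p and miR-7a-5p. The remaining 9 did not pass in edited cells, among them miR-222-5p. In the direct test 21 of the 31 differed between PDGF-BB and edited cells, where 179 of all 304 tested miRNAs (58.9%) did. The 31 were also chosen on the same PDGF-BB libraries, which favours a difference. miR-7a-5p rose after PDGF-BB and fell in edited cells (−0.36 ± 0.093), although with library totals the latter value was 0.089 and did not pass.

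**Figure D3:**
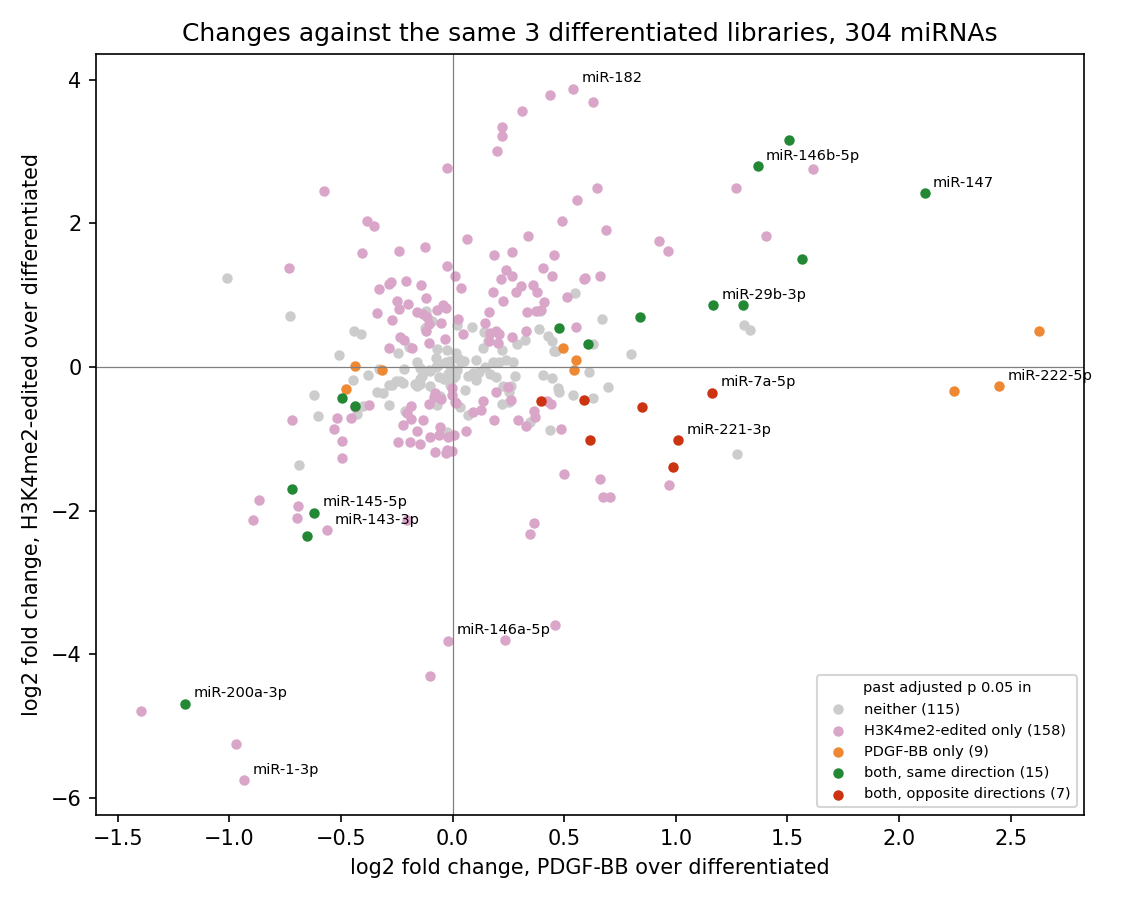
Log2 fold change over differentiated cells in PDGF-BB cells (horizontal axis) and in edited cells (vertical axis), 1 point per miRNA, for 304 miRNAs. Colours mark which of the comparisons passed an adjusted p of 0.05, and 15 miRNAs passed in both in the same direction and 7 in opposite directions, of which 4 no longer passed as lower in edited cells with library totals.

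Both comparisons share the same 3 differentiated libraries. Of the 15, 9 were higher and 6 lower in both, where independent lists of these sizes would share 7.09 and 2.43, and for the 7 in opposite directions 8.84. Across miRNAs, which are not independent replicates, the fold changes had a Pearson correlation of 0.34 and a covariance of 0.241. In 100 simulations of unchanged groups against the same controls, the mean correlation was 0.57 (0.46 to 0.77). The mean covariance was 0.0613, a difference of 0.180. The shared count had a mean of 0.01 there, but groups without changes pass almost no miRNAs, so a low count was fixed in advance. Those simulations show only what shared controls give to unchanged groups. Their correlation is no reference for that of groups with changes. The 3 controls were not split between the comparisons, so part of the overlap may come from the shared controls. The count of 15 was 9, 5 and 1 without differentiated replicates 1, 2 and 3, 6, 7 and 9 without PDGF-BB replicates 1, 2 and 3, and 30 without edited replicate 1.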

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

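The tests of scaling, of reads given to the wrong family member and of a share of unedited cells were chosen after the values were seen; the tests of sequencing depth and of other splits were written before their results were seen, although thinning itself was added after the data were seen.

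A group of 7 miRNAs rose after PDGF-BB and fell in edited cells, each against differentiated cells. Their choice by opposite directions against the same libraries all but fixes an edited minus PDGF-BB difference, so its size is given without a test. The log2 differences were −2.38 ± 0.20 for miR-222-3p, −2.03 ± 0.16 for miR-221-3p, −1.64 ± 0.15 for miR-125b-1-3p, −1.52 ± 0.10 for miR-7a-5p, −1.41 ± 0.17 for miR-449a-5p, −1.05 ± 0.11 for miR-99b-3p and −0.88 ± 0.10 for miR-324-3p. With library totals 3 of the 7, miR-221-3p, miR-222-3p and miR-125b-1-3p, remained lower in edited than in differentiated cells, and the other 4 did not pass that comparison. The 7 remained lower than in PDGF-BB cells under each of the 3 other scalings. Their choice all but fixes that as well, so nothing is concluded from it. Thinned to the smallest total, 5 of the 7 kept both calls. Of the 9 fits without 1 library, the call after PDGF-BB was kept in 1 for miR-324-3p, 2 for miR-125b-1-3p, 4 for miR-449a-5p, 5 for miR-222-3p, 7 for miR-99b-3p, 8 for miR-221-3p and 9 for miR-7a-5p.

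miR-221-3p and miR-222-3p, from neighbouring hairpins, are the 2 of 4 tested miR-221 and miR-222 arms that passed in opposite directions. Sequencing depth, which differs between the groups, is argued against by thinning each library to the smallest total, after which 2 of these 2 arms kept both calls; the bound written beforehand spoke of 3 arms, and 2 met the definition. Scaling of libraries whose composition differs is argued against by the 3 other scalings, under each of which both arms passed as higher after PDGF-BB and lower in edited cells than in differentiated cells; the smallest log2 change was 0.56, the fall of miR-221-3p with library totals (−0.56 ± 0.13). The call after PDGF-BB was lost without differentiated replicate 3 for miR-221-3p, and without differentiated replicates 2 or 3 or PDGF-BB replicates 1 or 2 for miR-222-3p. An effect of the treatments remains a hypothesis, and an effect of the lentivirus alone is confounded with editing here and may contribute.

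In edited cells miR-146a-5p fell and miR-146b-5p rose. Reads of the near-identical 5p arms given to the wrong member are argued against by the 3p arms, whose sequences differ: miR-146a-3p changed by −3.81 and miR-146b-3p by 3.16 on the log2 scale. In edited replicates 1, 2 and 3 miR-146a-5p kept 12.5%, 2.02% and 6.92% of its differentiated level. A set of 7 other miRNAs lost in edited cells kept 16.5% (95% exact Poisson interval 13.1 to 20.6), 2.97% (2.25 to 3.85) and 4.34% (3.20 to 5.76), on 78, 57 and 48 counts. These 7 were chosen for passing as lower and for a low mean level in edited replicates 2 and 3, so their low shares in those replicates were set by the choice. miR-582-3p carries 43, 12 and 30 of these counts, and without it the other 6 kept 8.66% (6.03 to 12.04), 2.74% and 1.90%. Whether miR-146a-5p lies below or above the limit in replicate 1, which has the most of it, thus rests on 1 miRNA. In replicate 3 miR-146a-5p lies above, but the set was chosen to be low there, so nothing is concluded from it. With so few counts a varying share of unedited cells that sets the level of miR-146a cannot be told apart from a change of miR-146a within the cells.

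Edited replicate 1 lies nearer the differentiated libraries than edited replicates 2 and 3. Of the 180 miRNAs that passed, 177 changed in the same direction in replicate 1 and 152 (84.4%) changed less, with a median size of 0.687 against 1.05 on the log2 scale. Lower depth is argued against by thinning, which left 0.953 of the gap on the first principal component (8.27 before, 7.88 after). A share of unedited cells in replicate 1 cannot be told apart from weaker editing. The 98 risen miRNAs need a share whose lower quartile is 21.5% (resampled interval 6.41 to 32.9) and whose median is 45.8% (40.0 to 51.1), while the lost miRNAs allow up to 20.6%, or 12.04% without miR-582-3p, limits that rest on 78 and 35 counts of miRNAs near the floor.

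The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05 (the smallest is 0.1). Every split but the real one puts libraries of both groups on each side, so a difference between the groups adds to the spread there. Low counts in those splits were thus all but fixed if the groups differ, and they are no reference for unchanged groups. The edgeR test passed 31, 180 and 179 miRNAs in the real splits of PDGF-BB against differentiated, edited against differentiated and edited against PDGF-BB, and 0 in the highest other split of each, or 74, 198 and 190 against 24, 31 and 30 at an unadjusted p under 0.05. In each of the 3 comparisons 1 of 10 splits reached the real count of miRNAs. The fry test passed 0, 9 and 10 lists in the real splits and 0 in the highest other split of each, or 6, 9 and 11 against 3, 3 and 1 at an unadjusted p under 0.05. As many lists as in the real split were passed in 10 of 10 splits for PDGF-BB and in 1 of 10 for each of the others.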

How the results depend on the processing

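Thinning to the smallest library total was chosen after the data were seen; the other settings were not. Over these settings 4415 values of named miRNAs were recomputed: 4081 kept their side of the threshold without a call being reversed, 280 no longer passed, 48 newly passed and 6 reversed; of 761 list values, judged by fry and its direction, 692, 42, 22 and 5 did so. The 4081 and 692 include 91 values that passed in neither fit and changed sign, and lists whose median changed sign.

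With library totals alone, let-7b-5p: H3K4me2-edited against differentiated came to 0.39, let-7f-5p: H3K4me2-edited against differentiated to 0.34, miR-31a-3p: H3K4me2-edited against differentiated to 0.10, let-7c-5p: H3K4me2-edited against PDGF-BB to 0.23, let-7f-5p: H3K4me2-edited against PDGF-BB to 0.23 and miR-181b-5p: H3K4me2-edited against PDGF-BB to 0.030, each with the sign reversed, since dropping the factors shifts edited libraries upwards. The let-7 list turned to medians of 0.36 (edited against differentiated) and 0.20 (edited against PDGF-BB) and, with no filter, to 0.026 (edited against differentiated); the de-differentiation list turned upwards by fry in edited against differentiated without passing, with its median at −0.28. Without edited replicate 2 the NF-kappaB list in edited against differentiated passed downwards by fry while its median was 0.85, and without differentiated replicates 1 and 2 its median was 1.03 and 0.62; the cause was not tested.

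PDGF-BB against differentiated passed 48 miRNAs with DESeq2, 11, 117 and 117 in the 3 comparisons passed an adjusted p of 0.01, and 12, 90 and 85 a fold of at least 2, which are stricter by construction. PDGF-BB lists past the fry test were 3 with library totals, 1 with the 6 compared libraries and 4 after thinning; the shared count was 25 with DESeq2. The causes were not tested. Leaving out 1 library gave 3 (without differentiated replicate 3) to 53 (without edited replicate 1) miRNAs and 0 to 4 lists for PDGF-BB, 139 to 207 and 7 to 10 for edited against differentiated, from 70 higher and 75 lower (without edited replicate 3) to 198 in all, and 8 to 12, for edited against PDGF-BB, and a shared count of 1 to 30.

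Same-numbered replicates deviated together in 4 of 9 pairs (correlations over 0.1, range −0.03 to 0.42), and 11 of 18 best matches had the same number. The highest correlation of any pair was between unlike numbers, at 0.52 for differentiated replicate 2 and PDGF-BB replicate 3, so a link between equal numbers is not shown. Something shared by equal numbers is not excluded either. With a block for the replicate number 29, 182 and, for edited against PDGF-BB, 2 more miRNAs than without it and 0, 8 and 10 lists passed, with 16 shared. Depth limits miRNAs near the floor, such as miR-1-3p in edited cells. Settings for normalized values were not run, since the table holds counts.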

Other observations

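The test of neighbouring hairpins and the pattern of miR-206-3p were chosen after the values were seen.

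Several miRNAs outside the lists changed in edited cells. miR-298-5p rose by 3.21 ± 0.23 on the log2 scale beside miR-296-3p, miR-204-5p by 2.48 ± 0.41, miR-190a-5p by 2.32 ± 0.25, and miR-140-3p, a miRNA of cartilage, by 1.79 ± 0.29.

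Arms from neighbouring hairpins changed together. Within clusters, the mean log2 change in edited cells was 3.87, 3.57 and 3.34 for the hairpins of miR-182, miR-96 and miR-183, −1.98 and −1.68 for miR-212 and miR-132, 1.72 and 1.27 for miR-27b and miR-23b, and 3.74 and 2.83 for miR-296 and miR-298. The cluster of miR-429, miR-200a and miR-200b changed by −5.25, −4.69 and −4.79, while the separate cluster of miR-200c and miR-141, related in sequence, rose, by 1.97 for miR-141. Over 171 hairpins, to which 259 of the 304 tested arms could be assigned, 55 pairs lie within 10 kb of each other in 27 clusters. Their mean absolute difference was 0.374 against 1.53 when the hairpins were shuffled (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give), and for PDGF-BB against differentiated it was 0.256 against 0.557 (permutation p = 0.0001). This is consistent with the hypothesis that neighbouring hairpins share their change, as hairpins of one primary transcript would, although families with similar sequences that share reads may add to it.

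miR-206-3p, a skeletal muscle miRNA, was highest in replicate 1 of each group, with 49.6, 7.68 and 9.20 CPM in differentiated replicates 1, 2 and 3, 28.8, 8.46 and 4.36 CPM in PDGF-BB replicates, and 19.4, 4.98 and 2.60 CPM in edited replicates.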
